A study of Mus musculus with 40 samples.

How the data were processed

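Total RNA was sequenced from frozen mouse hippocampus with MATQ-Drop, a droplet method that primes along whole transcripts rather than at the poly(A) tail. Per the labels, the tissue was Dounce homogenised, the homogenate was fixed with paraformaldehyde, and Hoechst-stained particles were sorted by flow cytometry. Hoechst-positive particles are nuclei; Hoechst-negative particles are called subneuronal compartments in the labels. The 40 samples came from female wild-type (WT) and 5XFAD mice of 9 months and from 1 WT male of 4 months. In the titles each sample carries a number, which was read as the mouse: 417 and 514 are WT, 418 and 480 are 5XFAD, and 778 is the male. Nuclei came in 13 libraries (8 WT, 5 5XFAD) and compartments of the same 4 mice in 22 (11 per genotype). A further 5 libraries hold compartments of mouse 778 taken from a density gradient.

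The deposited tables hold whole-number counts per gene and barcode, made by the authors. Per the submitters' processing notes the tools were cutadapt 3.1, UMI-tools, STAR 2.5.3a and featureCounts 2.0.1, with the mm10 build. The roles of these tools, the handling of molecular identifiers, the strand setting and the annotation were not given in the sources used here. Apart from mouse 778, which had a transcript count table alone, each mouse and sort had an exon, an intron and a transcript count table. In every barcode with all of these the transcript count equalled exon plus intron count, so transcript counts were the main measure. A lncRNA count table of the nuclei was used for 1 share. The name of the gradient table says that rRNA and mitochondrial genes were filtered out, yet rRNA-like genes took 18.4% of its counts; they were left out of all 3 totals in that comparison. No mitochondrial gene was listed in any table used, so neither a mitochondrial share nor the list of mitochondrially encoded genes could be measured. Ensembl gene identifiers were paired with symbols for 28920 of 29058 genes. No row lacked a gene.

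Barcodes were taken as deposited: 7356 nuclei and 21532 compartments. The nuclei of mice 417, 514, 418 and 480 numbered 3028, 1700, 1907 and 721, with totals of 46094869, 52968114, 53997415 and 31451530 counts. Compartments of the same mice numbered 7034, 4028, 6490 and 3980, with totals of 4637710, 3408968, 6977259 and 4498323 counts. Those of mouse 778 numbered 5958 and held 3389257 counts. Median counts per barcode lay between 10833.5 (417) and 21346 (480) in nuclei and between 409 (778) and 759.5 (480) in compartments. Intervals of counts and shares and floors of 3 counts cover counting error only, since it is not known whether counts are distinct molecules.

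Counts were summed per mouse and sort, so the replicate was the mouse (n = 4 per sort, n = 2 per genotype and sort). Sums were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. Compartments against nuclei was fitted on all 8 sums with sort and genotype as terms; 5XFAD against WT was fitted within each sort on 4 sums. An interaction term over the 8 sums tested whether the genotype effect differed between the sorts. Median log2 folds of compartments over nuclei were -0.29 with TMM, -0.18 with DESeq2 size factors and -0.56 with library size alone; within nuclei, library size alone moved the median genotype fold to 0.18. Biological coefficients of variation were 0.176, 0.136 and 0.221 in the sort, nuclei and compartment fits. RNA shared between particles was not estimated or removed. Counts of near-identical genes (C4b, H2-K1, haemoglobins, ribosomal proteins and their pseudogenes) can be split or shared between copies, and App can take reads of a human transgene.

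The same mice gave both sorts, so the numbers pair the samples across sorts. Deviations from the group means of nuclei and compartments over 17010 genes correlated at 0.0509 in mice 417 and 514 and at 0.148 in 418 and 480; with 2 mice per group the values within a genotype mirror each other. A fit with mouse as replicate block was run as the alternative.

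In all, 32 lists of genes were tested with camera in limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. They cover nuclear-retained lncRNA, postsynaptic density, dendritic mRNA, presynaptic, ribosomal protein, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, disease-associated and homeostatic microglia, reactive astrocyte, disease-associated oligodendrocyte, immediate-early, interferon response, complement, heat shock, amyloid processing and structural non-coding RNA genes. Markers of 15 cell classes make up the rest. Groups, designs, lists, markers and the rule for naming genes were fixed before the data were examined. The rule takes the 8 largest rises and the 8 largest falls past the threshold at 10 CPM or more whose groups do not overlap, leaving predicted gene models uncounted by name. It also takes up to 4 members of lowest p of each list, past the threshold or not, and always App, Thy1, Malat1, Meg3, Camk2a, Map2 and Xist; some genes that the rule takes are not reported here. With 2 mice against 2, sums that do not overlap between groups arise by chance in a share of 0.333 of genes. A fold against a group at 0 is a lower bound from a floor of 3 counts over the group, or over the summed libraries of a mouse beside the gradient sample; a group at 1 to 3 counts is given as a ratio with its 95% counting interval.

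Nuclei were clustered in scanpy 1.11.5 (counts scaled to 10000, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1). A cluster took a class name from 3 or more raised markers of a mean log2 of at least 0.75. It was called mixed where a second class reached a mean log2 of 1 and was detected in at least 20% of its nuclei, or where excitatory markers lay above -1 in a glial class. This naming rule went through 4 versions after the clusters, and before any genotype test, were seen. The last of them kept in the microglia class a cluster that also holds Cajal-Retzius markers. Compartments, clustered from 200 counts upwards, gave 11 clusters at resolution 1, none of which met the rule. Of these, cluster 2 held 2907 barcodes of mouse 417 against 49, 102 and 84 of mice 514, 418 and 480. At resolution 2 a cluster of 468 barcodes was named mixed microglia and another of 202 barcodes mixed astrocyte. Doublets were called per library with scrublet (532 nuclei, 7.23%) and removed before clustering. In 2 libraries the automatic threshold fell below the median score of simulated doublets, and 47.4% (mouse 418, library 2) and 67.5% (mouse 514, library 2) of nuclei were called. In the others the caller marked at most 1.11%, so it did not separate doublets from single nuclei here. Classes with at least 10 nuclei in each mouse were summed per mouse and tested in the same way. Single shares were compared with exact two-sided permutation tests.

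Each fit was tested on simulated data with 200 changed genes. At a 2-fold change it recovered 51% of them for compartments against nuclei, 56% for genotype in nuclei, 19% for genotype in compartments and 5% for the interaction; at a 4-fold change it recovered 85%, 84%, 82% and 49%. In the real data 13121 of 17010 genes differed between compartments and nuclei. The 51% and 85% for 200 changed genes thus do not describe recovery in that fit. In classes, recovery at a 4-fold change ran from 28% (microglia) to 92% (inhibitory neurons). Calls among unchanged genes numbered 7, 16, 14 and 4 in the first 4 fits and ran from 4 (microglia) to 11 (dentate) in classes. For genotype in nuclei and compartments, with at most 200 true calls, that is a larger share of calls than the stated 0.05. The same holds in microglia- and astrocyte-like nuclei, with 4 and 6 such calls, where at most 28% and 43% of changed genes were recovered. The other fits are not shown by these counts to keep to 0.05.

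The alternatives were DESeq2 1.42.0 and its size factors, library size alone, a filter minimum of 50 or none, exon or intron counts alone, count minimums per barcode, equal barcodes per mouse, removal of rRNA genes, the replicate block, each mouse left out, all 8 sums in 1 fit, equal numbers of each nuclear class, other Leiden resolutions and doublets kept. Further ones were added after the data had been seen: random draws of nuclei, nuclei without microglia clusters, thinning to the lowest total, the block on exon counts, doublet calls of 2 libraries not applied and, for lists, each mouse left out. In genotype fits with 1 mouse left out, 1 genotype keeps a single mouse, whose spread is then not measured. A call gained in such a fit is not support for a change. The gradient sample is 1 mouse and entered no test. No genome sequence was used here.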

Results

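Total RNA of single nuclei and of single Hoechst-negative compartments was measured in hippocampi of 2 WT and 2 5XFAD female mice of 9 months. 5XFAD mice carry human transgenes with familial Alzheimer mutations, APP among them, under Thy1 promoter elements, and deposit amyloid early. Between 721 and 3028 nuclei and between 3980 and 7034 compartments were counted per mouse. A nucleus held far more counts than a compartment: the median was 10833.5 to 21346 per nucleus and 472 to 759.5 per compartment in the 4 mice. The 5 rRNA-like genes took 0.442% to 0.824% of nuclear and 15.5% to 19.1% of compartment counts. A gradient preparation from 1 WT male of 4 months was described without a test.

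To ask whether the sorts separated nuclear precursor RNA from spliced cytoplasmic RNA, the intron share of counts was compared. Introns made up 81.4% ± 1.18 of nuclear counts and 9.69% ± 3.12 of compartment counts (SD, n = 4 mice each). The difference of -71.8 percentage points was larger than the spread between mice (exact permutation test, two-sided p = 0.0286, the smallest that 70 splits allow). All 4 mice showed it: with the mouse as replicate block, the exact sign-flip test gave p = 0.125, the smallest possible with 4 pairs. Compartment shares varied more than nuclear ones, from 6.77% in mouse 514 to 13.7% in mouse 417. Of 6237 clustered compartments of mouse 417, 2907 lay in a cluster that held 49, 102 and 84 of mice 514, 418 and 480. What sets that cluster apart was not tested, and comparisons of compartments that include mouse 417 carry it.

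**Figure D1:**
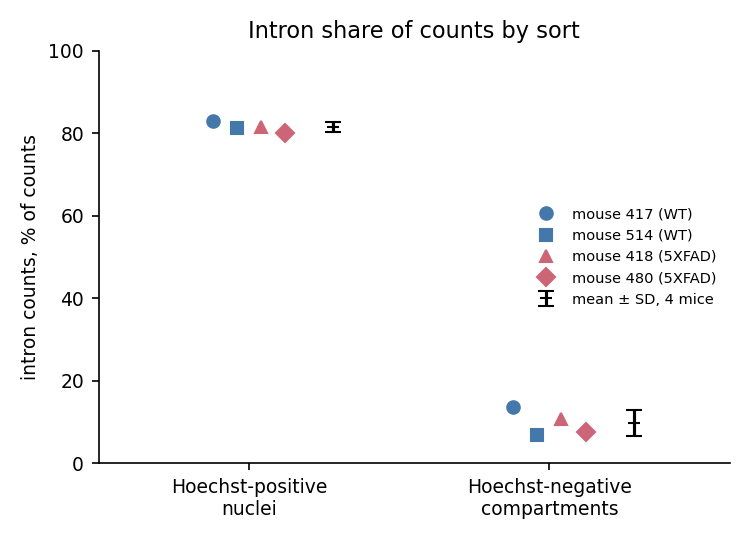
Intron counts as a percentage of all counts (vertical axis) in the nuclei and compartments of each mouse, with the mean ± SD of 4 mice. Nuclei lie between 80.04% and 82.9% and compartments between 6.77% and 13.7%.

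To find which transcripts set compartments apart from nuclei, summed counts were compared across both genotypes. Ribosomal protein and dendritic mRNAs were higher in compartments as lists at a preset correlation between genes (adjusted p = 0.225 and adjusted p = 0.335 with an estimated correlation). Rplp1, a protein of the ribosomal stalk, reached 117 ± 11.1 CPM in compartments and 1.39 ± 0.316 CPM in nuclei (SD, n = 4), a log2 fold of 6.41 ± 0.17 (SE). Camk2a, the synaptic kinase whose mRNA travels into dendrites, reached 7892 ± 1723 against 943 ± 246 CPM (3.07 ± 0.23), and Kif5a, a kinesin motor, 4608 ± 470.5 against 96.5 ± 7.05 CPM (5.58 ± 0.20). Nuclear-retained long non-coding RNAs were lower in compartments in the same way (adjusted p = 0.405 with an estimated correlation). Malat1 of nuclear speckles stood at 1829 ± 417 CPM in nuclei and 367 ± 51.8 CPM in compartments (-2.30 ± 0.18), and Xist, which coats the inactive X chromosome, at 1159.8 ± 212 and 96.5 ± 34.5 CPM (-3.61 ± 0.23). In all, 13121 of 17010 genes differed (edgeR), 5842 higher and 7279 lower in compartments. With library size alone the split was 5012 higher and 8256 lower. On exon counts alone 11130 of 14811 genes differed, and 8240 of these shared call and direction with the main fit. The main counts include introns, whose share differs between the sorts, so calls can depend on intron content.

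Y RNAs and ribosomal protein genes were among the largest rises in compartments. Rny1 and Rny3, the Y RNAs that bind the Ro60 protein, rose by log2 folds of 7.51 ± 0.47 and 5.79 ± 0.39, the first from 3.01 ± 2.02 to 539.9 ± 317 CPM. Mir703 followed at 7.39 ± 0.44, then the ribosomal genes Rps29 (6.26 ± 0.20) and Rps21 (5.99 ± 0.19), the elongation factor Eef1b2 (5.88 ± 0.20) and Fth1, the ferritin heavy chain (5.87 ± 0.19). The largest falls were Phxr4 (-5.79 ± 0.27), Sh3tc2, a Schwann-cell neuropathy gene (-5.18 ± 0.50), the potassium channel Kcnh8 (-4.97 ± 0.26), Lrmda (-4.94 ± 0.25), Mboat1 (-4.75 ± 0.26), Ninj2 (-4.67 ± 0.25), Prr5l (-4.65 ± 0.22) and Traf5 (-4.63 ± 0.38). Adjusted p of these 16 genes lay between 4.07e-08 (Rplp1) and 1.02e-05 (Sh3tc2).

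Of the 31 lists measured, 10 passed camera at its preset correlation and none did with an estimated one. All 45 ribosomal protein genes rose, with a median log2 fold of 4.31 (camera adjusted p = 1.43e-59, adjusted p = 0.225 with an estimated correlation). Of 13 dendritic mRNAs, 12 rose (median 3.71, adjusted p = 7.36e-10). Among them were Ddn, which encodes dendrin (5.45 ± 0.23), the elongation factor Eef1a1 (5.26 ± 0.16) and neurogranin, Nrgn (3.71 ± 0.23). All 7 heat shock genes rose too (median 4.41, adjusted p = 1.81e-06), such as the chaperone Hsp90aa1 (4.84 ± 0.15). For both of these lists the adjusted p = 0.335 with an estimated correlation. Of 19 presynaptic genes, 17 rose (median 2.52, adjusted p = 3.92e-08), with the vesicle-fusion genes Cplx2 at 4.39 ± 0.19 and Rab3a at 3.93 ± 0.15. Nuclear-encoded oxidative phosphorylation genes rose in 37 of 41 cases and fell in 2 (median 1.86, adjusted p = 3.12e-14), and Cox6a1 of complex IV rose by 5.44 ± 0.14. Both had adjusted p = 0.342 with an estimated correlation. Excitatory neuron markers rose in 7 of 8 cases (median 2.92, adjusted p = 0.00446), and disease-associated microglia genes rose in 16 of 23 and fell in 1 (median 2.19, adjusted p = 1.37e-05). These also had adjusted p = 0.342 with an estimated correlation. The microglia list includes widely expressed lysosomal genes such as the protease Ctsb (3.14 ± 0.13). All 14 immediate-early genes rose (median 2.91, adjusted p = 9.06e-07, adjusted p = 0.302 with an estimated correlation), such as the activity-induced factor Egr1 (3.49 ± 0.16). Inhibitory neuron markers rose in 8 cases and fell in 3 (median 2.25, adjusted p = 0.0488, adjusted p = 0.512 with an estimated correlation). With the mouse as replicate block their adjusted p was 0.0628, and it was 0.125 without mouse 417 and 0.0938 without 514. All 11 nuclear-retained lncRNAs measured fell (median -2.75, adjusted p = 0.00395, adjusted p = 0.405 with an estimated correlation). Neat1 of paraspeckles fell by 3.97 ± 0.24, Miat by 2.75 ± 0.18 and Meg3 by 1.35 ± 0.23.

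The other lists did not pass. Postsynaptic density genes went both ways, 8 up and 7 down of 18 (median 0.33, adjusted p = 0.169). Scaffolds of the density were among the rises, Shank1 at 3.28 ± 0.22 and Dlg4, which encodes PSD-95, at 2.71 ± 0.18. Astrocyte markers rose in 7 and fell in 3 of 10 cases (median 1.96, adjusted p = 0.0507), with the glutamate transporter Slc1a2 at 3.41 ± 0.23. They passed without mouse 417 (0.0304), 514 (0.0151), 418 (0.0191) or 480 (0.0395), and without these mice in turn 14, 12, 15 and 13 lists passed in all. Reactive astrocyte genes rose in 6 and fell in 2 of 10 cases (median 1.54, adjusted p = 0.0936), with Gfap, the astrocyte filament protein, at 5.27 ± 0.32. Structural non-coding RNAs rose in 4 of 5 cases (median 2.71, adjusted p = 0.103) and passed with the mouse as replicate block (0.000178). Disease-associated oligodendrocyte genes rose in 4 and fell in 1 of 6 cases (median 2.09, adjusted p = 0.0507), and complement genes rose in 7 of 9 (median 2.11, adjusted p = 0.0728). Homeostatic microglia genes rose in 8 and fell in 2 of 10 cases (median 0.85, adjusted p = 0.169), and microglia markers in 9 and 2 of 11 (median 0.94, adjusted p = 0.0728). Amyloid processing genes rose in 8 and fell in 2 of 13 cases (median 0.66, adjusted p = 0.103), and interferon genes in 5 and 2 of 12 (median 0.50, adjusted p = 0.742). Among neuronal layers, dentate granule markers had a median of -0.94 (adjusted p = 0.0687), CA1 markers 0.25 (0.737) and CA3 markers -0.82 (0.546). Oligodendrocyte markers were at -0.02 (adjusted p = 0.646) and those of their precursors (OPC) at -0.92 (0.737). Medians of vascular and other lists were -0.14 for endothelial (adjusted p = 0.88), 0.51 for pericyte (0.889), 2.22 for choroid (0.569) and 1.03 for fibroblast markers (0.742). Erythrocyte markers were at 5.85 (adjusted p = 0.199) and Cajal-Retzius markers at 0.52, with a mean of -0.33 (0.88). Adjusted over the list alone, counts were the same except for interferon (4 up, 1 down), endothelial (1 up against 1 up and 1 down) and Cajal-Retzius genes (2 up and 1 down against 1 up and 1 down).

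Map2, a dendritic microtubule protein, rose by 2.23 ± 0.15, App, the amyloid precursor, by 1.77 ± 0.15, and Thy1, a neuronal surface protein, by 3.91 ± 0.17. On intron counts 2131 genes differed. The log2 folds of Camk2a, Kif5a, Nrgn, Cplx2, Rab3a, Fth1, Cox6a1, Ctsb, App and Meg3 then changed sign. Camk2a, App and Cplx2 were nearly level between the sorts on these counts.

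**Figure D2:**
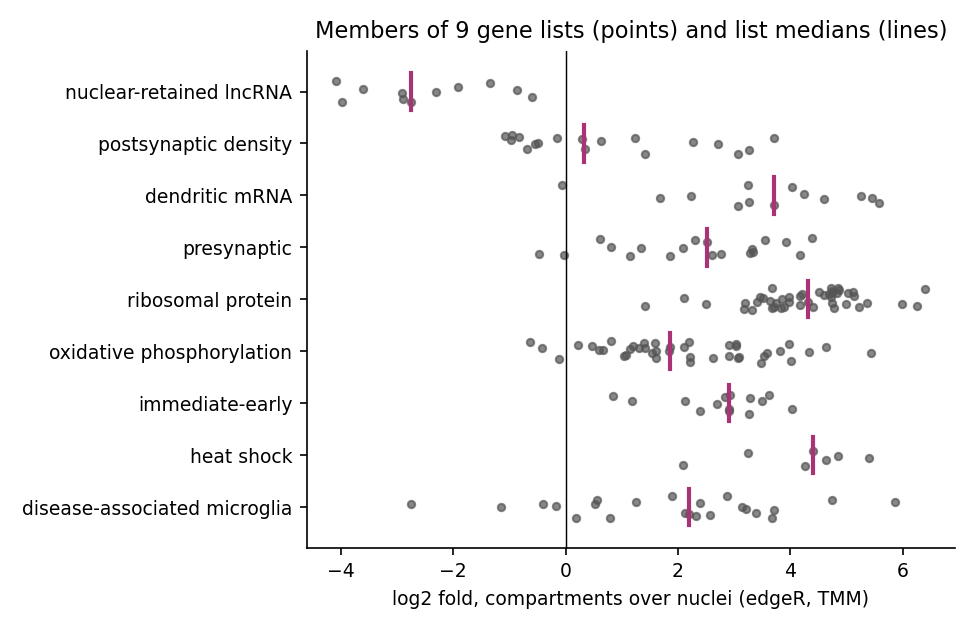
Log2 folds of compartments over nuclei (horizontal axis, edgeR with TMM scaling) of the members of 9 lists, with lines at list medians. Medians run from -2.75 for nuclear-retained lncRNA to 4.41 for heat shock genes; those of postsynaptic density (0.33) lie nearest to 0.

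To ask how 5XFAD changed nuclear RNA, the nuclei of 2 5XFAD and 2 WT mice were compared. Microglial genes were among the largest rises and astrocyte genes among the largest falls. Itgax, the integrin CD11c of plaque-associated microglia, rose from 0.297 ± 0.246 to 15.9 ± 9.22 CPM (SD, n = 2 per group), a log2 fold of 5.65 ± 0.62 (SE, adjusted p = 0.0059). Trem2, the lipid-sensing microglial receptor, rose from 3.26 ± 0.669 to 18.7 ± 2.5 CPM (2.51 ± 0.19, adjusted p = 0.00176), and C4b, complement component 4, from 24.8 ± 9.50 to 139 ± 9.31 CPM (2.49 ± 0.25, adjusted p = 0.00443). Gja1, connexin 43 of astrocytes, fell from 32.5 ± 3.01 to 7.20 ± 2.92 CPM (-2.16 ± 0.26, adjusted p = 0.00775), and Slc1a3, an astrocyte glutamate transporter, from 282 ± 32.4 to 122 ± 25.2 CPM (-1.20 ± 0.17, adjusted p = 0.0145). In all, 799 of 17550 genes differed (560 higher, 239 lower). With equal numbers of each named class per mouse (307 nuclei), 8 genes differed, against 334 to 659 in 5 random draws of as many nuclei; C4b (2.84) and Thy1 (1.89) were among the 8. Without the clusters of microglia, mixed ones included, 40 genes differed, C4b (2.76) and Thy1 (1.54) among them; the 532 nuclei called doublets have no cluster and stay in this sum.

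The largest other rises were in Tent5c, a poly(A) polymerase (3.45 ± 0.29), the lysosomal transporter Slc15a3 (3.36 ± 0.18), Nlrc5, an activator of MHC class I genes (3.04 ± 0.17), Samsn1 (2.90 ± 0.21), Flt1, a receptor for VEGF (2.88 ± 0.41), AU020206, a non-coding gene (2.83 ± 0.11), and Cd180, a Toll-like receptor homologue (2.82 ± 0.25). The largest falls included Cd38, an NAD-consuming enzyme (-2.45 ± 0.21), Dio2, the thyroid hormone deiodinase of astrocytes (-2.26 ± 0.25), Slco1c1, a thyroid hormone transporter (-2.23 ± 0.16), Sdc4 (-1.91 ± 0.26), Gjb6, connexin 30 (-1.90 ± 0.31), Fam20a (-1.89 ± 0.30) and Plcd4 (-1.88 ± 0.26). Adjusted p of the 16 named largest changes was at most 0.0221. Without mouse 514 the calls of Gjb6 (0.0590) and Fam20a (0.0514) were lost.

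Of 30 lists, 9 passed camera and none with an estimated correlation; 12 passed on exon counts, 7 of the 9 among them. Without mice 417, 514, 418 and 480 in turn 8, 18, 15 and 9 passed. Disease-associated microglia genes rose in 15 of 23 cases, with 17 rises and 1 fall adjusted over the list alone (median 1.54, camera adjusted p = 2.42e-30, adjusted p = 0.324 with an estimated correlation). Clec7a, a phagocytic receptor, had 593 counts against 1 in WT (ratio 687, interval 123 to 27199). Cst7, an inhibitor of cathepsins, had 646 against 2 (ratio 374, interval 103 to 3099), and the cathepsin Ctsz rose by 1.53 ± 0.12. Homeostatic microglia genes rose in 7 of 10 cases (9 adjusted over the list alone, median 1.17, adjusted p = 3.22e-20). The fractalkine receptor Cx3cr1 rose by 1.21 ± 0.10 and the growth factor receptor Csf1r by 1.29 ± 0.14. Microglia markers rose in 8 of 11 cases (10 adjusted over the list alone, median 1.23, adjusted p = 7.99e-23), with the protease Ctss at 1.79 ± 0.14 and the phosphatase Inpp5d at 1.69 ± 0.17. Both lists had adjusted p = 0.324 with an estimated correlation. With equal class numbers, Cx3cr1, Csf1r, Ctss and Inpp5d lay lower in 5XFAD. Complement genes rose in 4 of 9 cases, with 7 rises and 1 fall adjusted over the list alone (median 1.29, adjusted p = 1.07e-09, adjusted p = 0.324 with an estimated correlation). C3ar1, a receptor for C3a, rose by 2.89 ± 0.24. Interferon response genes rose in 4 of 11 cases (8 adjusted over the list alone, median 0.95, adjusted p = 6.92e-07, adjusted p = 0.712 with an estimated correlation), Oasl2 by 2.48 ± 0.30 and Oas1a by 3.54 ± 0.52. Disease-associated oligodendrocyte genes rose in 5 of 6 cases (6 adjusted over the list alone, median 1.33, adjusted p = 4.29e-11). The list had adjusted p = 0.324 with an estimated correlation and 0.0349 by fry. Its members were also counted in classes other than oligodendrocytes, such as C4b in astrocyte-like and H2-K1 in microglia-like nuclei. H2-K1, an MHC class I gene, rose by 1.64 ± 0.18 over all nuclei.

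Astrocyte markers fell in 8 of 10 cases (9 adjusted over the list alone, median -1.35, camera adjusted p = 1.33e-17, adjusted p = 0.426 with an estimated correlation), among them Aldh1l1, a folate enzyme (-1.57 ± 0.21). Postsynaptic density genes (median -0.31, adjusted p = 0.00493) and dentate granule markers (median -0.34, adjusted p = 0.0216) lay lower as lists, each with adjusted p = 0.790 with an estimated correlation, while none of their 18 and 8 members passed alone; Gria2, a glutamate receptor subunit, was at -0.47 ± 0.19 (0.328) and Stxbp6 at -0.58 ± 0.21 (0.263). Neither list passed on exon counts (0.235 and 0.238) or without mouse 417 (0.514 and 0.17), nor the first without 480 (0.0642) and the second without 418 (0.201). Postsynaptic density genes summed to 24570.3, 15980 (WT), 16025 and 13001 CPM (5XFAD) in mice 417, 514, 418 and 480, so mouse 417 stood apart. Reactive astrocyte genes did not pass as a list (median 0.16, adjusted p = 0.0847), with 2 of 10 risen, C4b and the protease inhibitor Serpina3n (0.74 ± 0.13, 3 up and 1 down adjusted over the list alone). The chaperones Hsp90ab1 (-0.51 ± 0.09, adjusted p = 0.0341) and Hsp90aa1 (-0.60 ± 0.12, adjusted p = 0.0468) fell of 6 heat shock genes (median -0.18, adjusted p = 0.17). Serpina3n lost its call without mouse 417 (0.0637), 514 (0.0734), 418 (0.0846) or 480 (0.146). Hsp90aa1 did likewise (0.106, 0.112, 0.205 and 0.2), and Hsp90ab1 without 514 (0.103), 418 (0.139) or 480 (0.196).

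The other lists of neuronal and housekeeping genes did not pass, and no member did over all genes. Their medians were -0.25 for nuclear-retained lncRNA (adjusted p = 0.164), -0.24 for dendritic (0.0847), -0.15 for presynaptic (0.0787), -0.12 for ribosomal (0.17) and -0.06 for oxidative phosphorylation genes (0.0847). Immediate-early genes were at -0.05 (adjusted p = 0.657), amyloid processing genes at -0.05 (0.35, with 1 fall adjusted over the list alone) and structural RNAs at -0.58 (0.35). Among marker lists, oligodendrocyte markers were higher in all 10 cases without passing (median 0.29, adjusted p = 0.0787). Excitatory (-0.20), inhibitory (-0.25), CA1 (-0.03), CA3 (-0.01), OPC (-0.18), Cajal-Retzius (-0.04), choroid (0.47), pericyte (-0.54) and fibroblast markers (-0.85) had medians of either sign, with 1 fall adjusted over the list alone in each of the last pair. Flt1 was the 1 of 6 endothelial markers that rose (list median 0.07, adjusted p = 0.543). Malat1 (-0.42 ± 0.29), Meg3 (-0.45), Camk2a (-0.46), Map2 (-0.24) and Xist (-0.32) did not pass (adjusted p = 0.511 to 0.657). Long non-coding RNA took 2.63% ± 0.0708 of nuclear counts in WT and 2.67% ± 0.0171 in 5XFAD (SD, n = 2). The difference of 0.0380 percentage points was within the spread between mice (exact permutation test, p = 1, smallest possible 0.333).

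**Figure D3:**
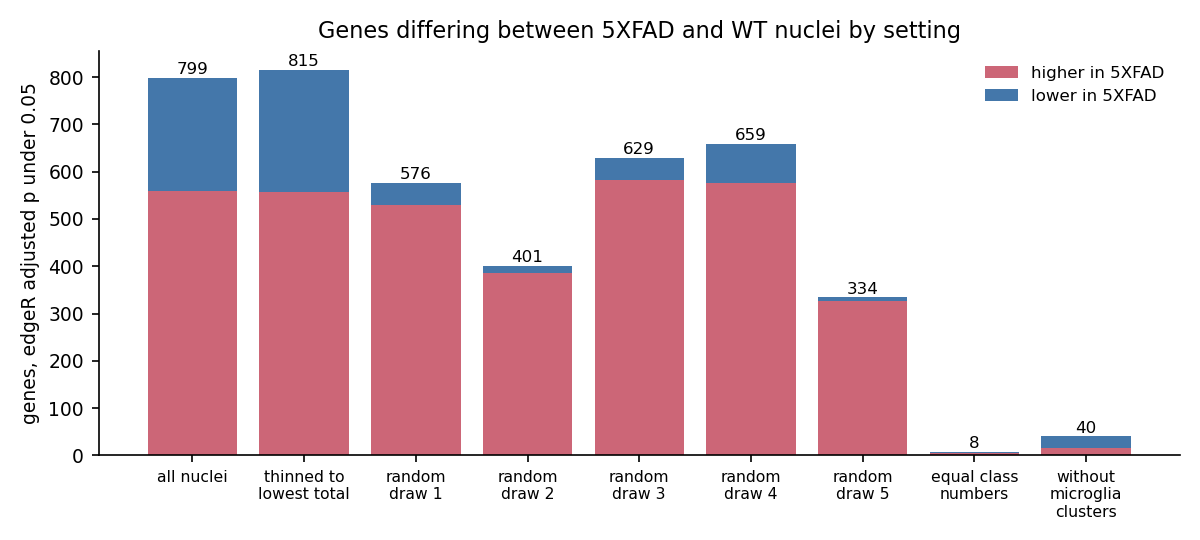
Genes past an edgeR adjusted p of 0.05 between 5XFAD and WT nuclei (vertical axis, higher and lower stacked) with all nuclei and under 8 other settings. The count is 799 with all nuclei, 815 after thinning, 334 to 659 in random draws, 8 with equal class numbers and 40 without microglia clusters.

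To ask whether 5XFAD also changed RNA outside nuclei, compartments of the same mice were compared. Members of the microglia lists, Thy1 and C4b were among the genes that passed. Cst7 had 729 counts in 5XFAD and 0 in WT, at least 170.4-fold higher. Cd68, a lysosomal protein of phagocytes, rose from 3.03 ± 0.490 to 39.0 ± 3.12 CPM (SD, n = 2, log2 fold 3.66 ± 0.28, SE), and C1qc, a chain of complement C1q, from 7.88 ± 1.91 to 52.3 ± 0.532 CPM (2.74 ± 0.26). Thy1 rose from 471 ± 73.7 to 2503 ± 33.3 CPM (2.41 ± 0.21). In all, 16 of 12311 genes differed by edgeR, all higher in 5XFAD, and 624 at an unadjusted p under 0.05. DESeq2 called 67 (60 higher, 7 lower) and exon counts 52 (all higher). With no low-count filter 180 were higher and 128 lower, so the single direction does not hold in every setting. Besides Cst7, Cd68, C1qc and Thy1, Lyz2, a lysozyme (4.57 ± 0.42), the pore-forming Mpeg1 (4.21 ± 0.30), AU020206 (3.61 ± 0.28), the Fc receptor genes Fcgr2b (3.47 ± 0.35) and Fcer1g (2.95 ± 0.32), Cd180 (3.07 ± 0.33), C4b (2.63 ± 0.25), Cx3cr1 (2.08 ± 0.20) and Csf1r (1.95 ± 0.22) rose, with adjusted p between 0.0123 and 0.0354. Without mouse 417 only 8 genes passed; lost were C1qc (0.0506), C4b (0.0535), Csf1r (0.0553), Lyz2 (0.102), Fcgr2b (0.104), Fcer1g (0.110), Cd180 (0.111) and others. Without mouse 480 Csf1r was lost (0.0660), and 31 genes passed; without 418 it was 34, and without 514 it was 310.

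Of 27 lists, 16 passed camera, none with an estimated correlation and none by fry. Without mice 417, 514, 418 and 480 in turn 14, 18, 14 and 15 passed. Disease-associated microglia genes rose in 2 of 23 cases and in 19 adjusted over the list alone (camera adjusted p = 1.8e-78, adjusted p = 0.101 with an estimated correlation). Their median was 1.80, also with the 3 members at 0 in WT set to their lower bound. Itgax had 226 counts against 0 (at least 52.8-fold, adjusted p = 0.0603) and Gpnmb, a lysosomal glycoprotein, was at 3.09 ± 0.38 (adjusted p = 0.0551). Fits with 1 mouse left out keep a single mouse in 1 group, so they cannot settle these calls. Complement genes rose in 2 of 9 cases (7 adjusted over the list alone, median 2.5, adjusted p = 3.4e-36). Homeostatic microglia genes rose in 2 of 10 (7 adjusted over the list alone, median 1.37, adjusted p = 1.32e-26). Either list had adjusted p = 0.101 with an estimated correlation. Microglia markers rose in 3 of 11 cases (9 adjusted over the list alone, median 1.95, adjusted p = 1.88e-42, adjusted p = 0.115 with an estimated correlation). C4b was the only one of 9 reactive astrocyte genes that rose (5 adjusted over the list alone, median 1.71, adjusted p = 7.04e-15). It was also the only one of 6 disease-associated oligodendrocyte genes (5 adjusted over the list alone, median 1.84, adjusted p = 2.79e-22). Both had adjusted p = 0.115 with an estimated correlation. B2m, the light chain of MHC class I, was at 1.70 ± 0.22 (adjusted p = 0.0608). Gfap stood at 1782 ± 130.0 against 210.1 ± 142 CPM (3.09 ± 0.47, adjusted p = 0.0911). Its WT spread was wide, and the same limit holds for its fits with 1 mouse left out.

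The remaining lists that passed had no member past the threshold over all genes. Interferon genes were higher in 5XFAD (median 0.65, adjusted p = 0.000714, 1 of 7 adjusted over the list alone), with adjusted p = 0.240 with an estimated correlation. Amyloid processing genes were higher (median 0.17, adjusted p = 0.00091), with 2 of 13, App among them, risen adjusted over the list alone. Markers of dentate granule cells (median 0.63, adjusted p = 0.00523), CA3 (median 0.47, adjusted p = 0.00852) and choroid plexus (median 1.72, adjusted p = 0.0011) were higher as well. All 4 had adjusted p = 0.451 with an estimated correlation. Choroid markers summed to 15, 55.4, 49.5 and 432 CPM in mice 417, 514, 418 and 480, so mouse 480 stood apart and 418 lay below WT mouse 514. Choroid markers lost their call without 417 (0.0985) or 480 (0.0784), dentate markers without 417 (0.108) and CA3 markers without 417 (0.637) or 418 (0.0944). Oligodendrocyte markers (median 0.60, adjusted p = 0.000265, adjusted p = 0.490 with an estimated correlation) and dendritic mRNAs (median 0.30, adjusted p = 0.0113, adjusted p = 0.561 with an estimated correlation) followed. Mouse 417 stood apart in both sums, at 1664 CPM against 4127, 4699 and 4213 CPM and at 20387 against 28049, 28591 and 29416 CPM in mice 514, 418 and 480. Without it neither list passed (0.331 and 0.784), nor did dendritic mRNAs without 480 (0.103). Oxidative phosphorylation genes were lower (median -0.22, adjusted p = 0.00337, adjusted p = 0.707 with an estimated correlation), with Cox5a at -0.69 ± 0.27 (0.919). Immediate-early genes were lower (median -0.27, adjusted p = 0.0113, adjusted p = 0.303 with an estimated correlation), with the phosphatase Dusp1 at -0.89 ± 0.25 (0.580). Sums of the last 2 lists overlapped between the genotypes, at 1590 and 2135 against 1392 and 1860 CPM and at 671 and 987 against 760.4 and 766 CPM. Neither passed without mouse 514 (0.932, with the direction turned, and 0.453) or 418 (0.975 and 0.141). Inhibitory markers were lower as well (median -0.39, adjusted p = 0.00091, adjusted p = 0.245 with an estimated correlation), with Adarb2 at -1.07 ± 0.39 (0.871). Mouse 417 stood apart from the rest here too, with a sum of 1406 CPM against 915, 714 and 788 CPM in mice 514, 418 and 480, but the list passed when any 1 mouse was left out. Without mouse 514, which leaves a single WT mouse, Adarb2 was at -1.54 and Camk2a at 0.83. Astrocyte markers did not pass (median -0.38, adjusted p = 0.0932, 1 up and 2 down adjusted over the list alone). Nor did structural RNA (median -0.28, adjusted p = 0.0546), presynaptic (0.08, 0.512), postsynaptic density (0.17, 0.215), ribosomal (0.09, 0.308), heat shock (-0.07, 0.583) and nuclear-retained lncRNA genes (0.08, 0.288). Excitatory (0.29, 0.411), CA1 (-0.04, 0.411), OPC (0.08, 0.893) and pericyte markers (0.02, 0.857) also missed the threshold. With all mice Camk2a was at 0.40, Map2 at 0.03, Malat1 at 0.21, Meg3 at -0.07 and Xist at -0.57 (adjusted p = 0.985 to 0.998).

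The transgenes combine human coding sequence, that of APP included, with mouse Thy1 elements, so the mouse genes App (ENSMUSG00000022892.10) and Thy1 (ENSMUSG00000032011.4) were followed in exon and intron counts apart. In nuclei App showed no detectable change in all counts (-0.06 ± 0.17, adjusted p = 0.937), while Thy1 rose from 52.5 ± 12.1 to 144 ± 4.92 CPM (SD, n = 2, 1.46 ± 0.16, adjusted p = 0.00628). In compartments App reached 2801 ± 237 against 973 ± 61.6 CPM (1.53 ± 0.20, adjusted p = 0.0603). It passed on exon counts alone (1.61 ± 0.18, adjusted p = 0.0121). Its intron fold in compartments was -0.92 ± 0.51. In nuclei its exon fold was 0.33 ± 0.14 and its intron fold -0.14 ± 0.19. Thy1 rose in both: 1.44 ± 0.19 on exons and 1.5 ± 0.15 on introns of nuclei.

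**Figure D4:**
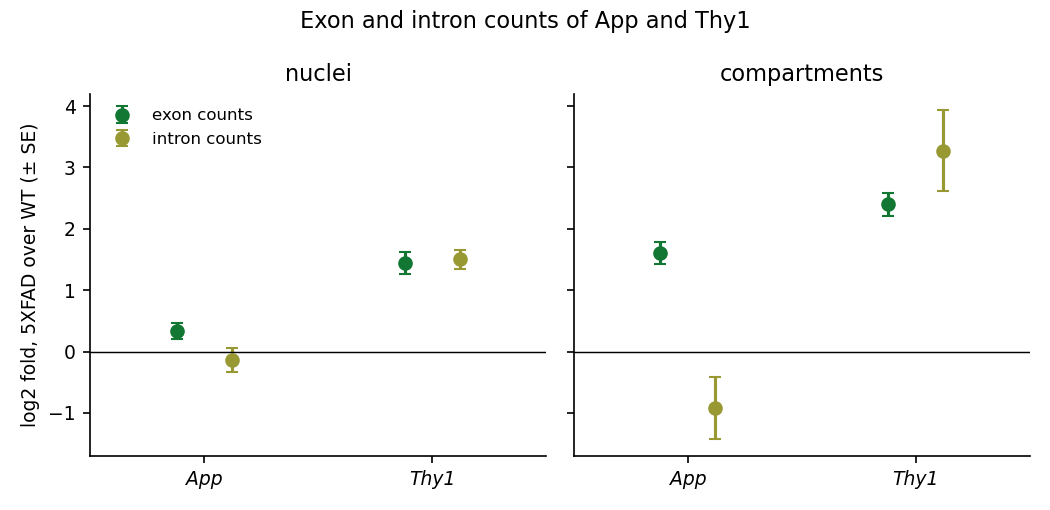
Log2 folds (± SE) of 5XFAD over WT (vertical axis) for App and Thy1 on exon and intron counts, in nuclei and in compartments. The exon fold of App in compartments is 1.61, and Thy1 lies between 1.44 and 3.27 on both kinds of count.

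To ask whether the genotype effect differed between the sorts, the interaction was tested. Astrocyte markers had the lowest p of the lists, though not the largest median: they fell in nuclei, and the effect in compartments lay higher by a median of 1.03 (camera adjusted p = 2.43e-14, 7 of the members adjusted over the list alone, adjusted p = 0.183 with an estimated correlation). Gja1 was at 1.32 ± 0.36 (0.654), the water channel Aqp4 at 1.45 ± 0.38 (0.590) and Aldh1l1 at 1.13 ± 0.33 (0.682). No gene of 17010 passed by edgeR (986 at an unadjusted p under 0.05, DESeq2 called 59). Gfap was at 2.93 ± 0.56 (0.409) with all mice and at 3.5 without mouse 514, a fit that leaves a single WT mouse. App (1.56 ± 0.29, adjusted p = 0.409), Cd68 (1.90 ± 0.34, adjusted p = 0.409), C1qc (1.45 ± 0.29, adjusted p = 0.415), Thy1 (0.94 ± 0.31, adjusted p = 0.753), Camk2a (0.85), Malat1 (0.60), Meg3 (0.35), Map2 (0.24) and Xist (-0.26) did not pass.

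Of 31 lists, 13 passed camera in the interaction, all higher in compartments, and none passed with an estimated correlation or by fry. Besides astrocyte markers these were reactive astrocyte (median 1.0, adjusted p = 3.81e-07), complement (median 1.18, adjusted p = 0.000185) and amyloid processing genes (median 0.24, adjusted p = 2.84e-05), each with adjusted p = 0.183 with an estimated correlation. Disease-associated microglia genes (median 0.55, adjusted p = 3.81e-07, adjusted p = 0.314 with an estimated correlation) and dentate markers (median 1.06, adjusted p = 1.65e-05, adjusted p = 0.267 with an estimated correlation) followed. Microglia markers (median 0.62, adjusted p = 0.000642), dendritic (median 0.49, adjusted p = 0.000356) and nuclear-retained lncRNA genes (median 0.28, adjusted p = 0.0106) and CA3 markers (median 0.55, adjusted p = 0.0126) had adjusted p = 0.501 with an estimated correlation. Postsynaptic density genes (median 0.40, adjusted p = 0.000185) had adjusted p = 0.557 with an estimated correlation, and ribosomal (median 0.18, adjusted p = 0.00493) and presynaptic genes (median 0.27, adjusted p = 0.0344) adjusted p = 0.681 with an estimated correlation. With the mouse as replicate block, oligodendrocyte markers passed as well (0.0245). Without mouse 417, which stood apart in neuronal lists of both sorts, postsynaptic density (0.502), dendritic (0.822), presynaptic (0.895) and ribosomal genes (0.801, with the direction turned) and CA3 markers (0.801) lost their calls. Presynaptic genes also lost theirs without 418 (0.106) or 480 (0.154), ribosomal genes (0.154) and microglia markers (0.0884) without 480, CA3 markers without 418 (0.178) and nuclear-retained lncRNA without 514 (0.125). In all, 12, 15, 11 and 15 lists passed without mice 417, 514, 418 and 480.

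To ask which kinds of nuclei the sorts held, nuclei were clustered and classes were named from markers. Microglia-like nuclei made up 1.76% and 1.80% of nuclei in WT mice 417 and 514 and 13.3% and 11.4% in 5XFAD mice 418 and 480, and oligodendrocyte-like nuclei 4.98% and 8.13% against 18.1% and 13.4%. The differences of 10.6 and 9.16 percentage points exceed the spread between mice, but with 2 mice per group an exact test cannot go below 0.333. Astrocyte-like nuclei took 4.26% ± 0.293 in WT and 2.67% ± 1.02 in 5XFAD, and mixed astrocyte clusters 11.7% and 21.7% against 3.07% and 3.62%. Mixed microglia clusters took 2.52% and 2.60% against 9.84% and 19.6%. Shares of CA1 pyramidal-like (4.89% ± 0.436 and 3.41% ± 0.300), dentate granule-like (16.4% ± 5.32 and 11.99% ± 2.15), inhibitory neuron-like (5.59% ± 1.99 and 4.74% ± 1.19) and OPC-like nuclei (1.90% ± 0.0520 and 3.49% ± 1.19) differed by smaller amounts. Mixed oligodendrocyte clusters took 3.49% and 5.07% in WT against 3.45% and 5.71% in 5XFAD, and mixed OPC clusters 1.76% and 2.87% against 1.69% and 2.23%. WT microglia-like nuclei lay mostly in cluster 13 and 5XFAD ones in cluster 26; oligodendrocyte-like nuclei of mouse 417 lay mostly in cluster 23 and those of the other mice in 25. With doublets kept, the microglia class held 0% and 0.0588% of WT nuclei (0 and 1) and 8.65% and 8.18% of 5XFAD nuclei, so the WT class depends on the handling of doublets. Unnamed clusters held 36.0%, 24.1%, 20.8% and 17.3% of nuclei in mice 417, 514, 418 and 480. Depth per nucleus and the sort differ between mice and can set such shares.

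**Figure D5:**
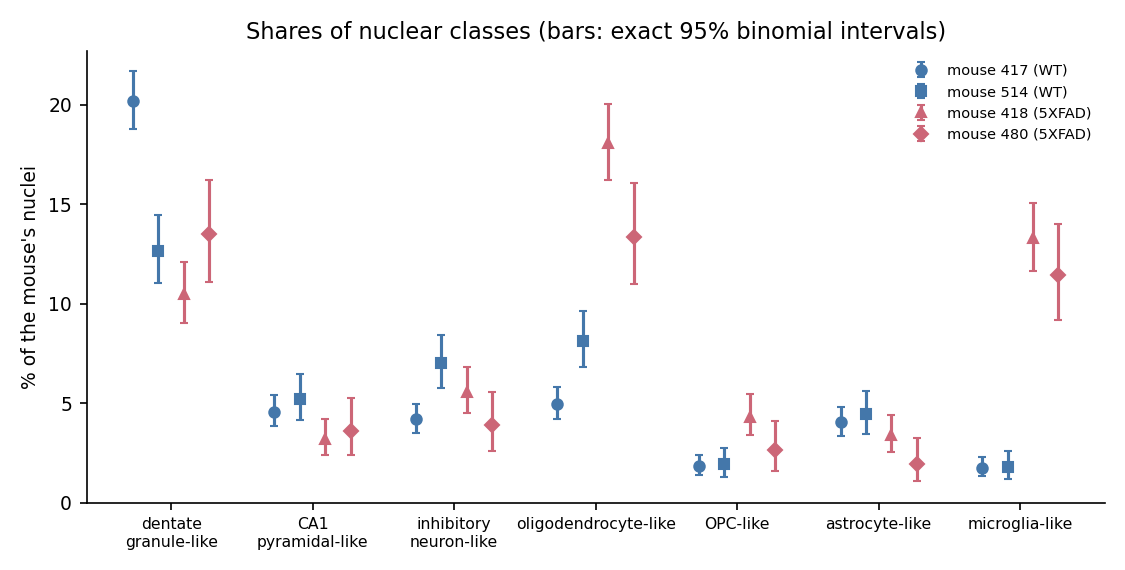
Share of each mouse's nuclei (vertical axis, percent) in 7 named classes, with exact 95% binomial intervals that cover counting error only. Microglia-like nuclei lie at 1.76% and 1.80% in WT and at 13.3% and 11.4% in 5XFAD mice.

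To ask which classes carried the genotype changes, sums per class were tested. C4b (ENSMUSG00000073418.4) counts rose in 2 classes by edgeR. In OPC-like nuclei they went from 5.75 ± 0.475 to 149 ± 10.8 CPM (SD, n = 2, log2 fold 4.64 ± 0.39, SE, adjusted p = 0.00203). In inhibitory neuron-like nuclei (clusters 3 and 8) they went from 5.29 ± 4.79 to 83.9 ± 0.0172 CPM (3.98 ± 0.38, adjusted p = 0.00607, 0.0589 by DESeq2). RNA shared between particles was not removed, and C4b stood at 1273 ± 26.8 CPM in 5XFAD oligodendrocyte-like nuclei. In inhibitory neuron-like nuclei oligodendrocyte (median 0.38) and OPC markers (median 0.47) were also higher as lists, the first not without mouse 417 (0.275) and the second not without 480 (0.955), each with adjusted p = 0.567 with an estimated correlation, and Gfap was at 2.84 ± 0.86 (0.468). Thy1 rose in dentate granule-like nuclei from 51.2 ± 8.28 to 185 ± 2.35 CPM (1.84 ± 0.13, adjusted p = 0.00299) and was at 2.03 ± 0.20 in CA1-like nuclei (0.0636). Most dentate nuclei of mouse 417 lay in cluster 15, those of the others in 16. C4b and Thy1 were the only genes past the threshold by edgeR in OPC-like, inhibitory and dentate nuclei, with 425, 695 and 497 genes at an unadjusted p under 0.05 and 7, 0 and 7 calls by DESeq2. Without mice 417, 514, 418 and 480 in turn, counts were 70, 64, 168 and 71 in OPC-like, 27, 1, 289 and 169 in inhibitory and 123, 374, 0 and 0 in dentate nuclei; the mouse left alone in its group is then assumed to vary like the others. Thy1 in dentate nuclei was lost without 418 or 480. Calls of Thy1 gained in CA1-like nuclei with 1 mouse left out are not support for a change.

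No gene passed by edgeR in CA1-like (551 at an unadjusted p under 0.05, DESeq2 3), astrocyte-like (247, DESeq2 0) and oligodendrocyte-like nuclei (665, DESeq2 18). On simulated data a 2-fold change was recovered for 29%, 4% and 2% of genes in these classes, and a 4-fold change for 85%, 43% and 58%. Mouse 480 had 14 astrocyte-like nuclei. The lack of calls is thus no sign of a lack of change. In oligodendrocyte-like nuclei C4b stood at 1273 ± 26.8 against 125 ± 129 CPM (3.37 ± 0.83, adjusted p = 0.584) and Serpina3n at 55.0 ± 9.46 against 3.55 ± 1.66 CPM (3.98 ± 0.43, adjusted p = 0.470). Fits without mouse 417 or 514 leave a single WT mouse, whose spread is not measured, so they cannot settle these genes. Gfap was at 2.36 ± 0.49 there (0.584), at 1.57 ± 0.29 in astrocyte-like nuclei (0.995), and in inhibitory neuron-like nuclei it passed without mouse 418 (3.77, adjusted p = 0.00326), where Serpina3n was at 1.37 ± 0.53 (0.667). In astrocyte-like nuclei C4b was at 1.6 ± 0.43 (0.995). Calls of C4b and Gfap gained there without mouse 514 are not support for a change. Counts without mice 417, 514, 418 and 480 were 12, 14, 70 and 69 in CA1-like, 0, 478, 0 and 0 in astrocyte-like and 171, 1553, 0 and 0 in oligodendrocyte-like nuclei.

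In microglia-like nuclei (53 and 27 in WT, 212 and 82 in 5XFAD) 83 of 7025 genes passed, 20 higher and 63 lower, all close to the threshold. At Leiden resolution 0.5 the size of the class differed in mouse 480 alone (83 nuclei in place of 82), and 0 genes passed. The calls thus depend on very small changes of the class. Clec7a had 210 counts against 0 (at least 17.2-fold, 0.0483). Igf1, insulin-like growth factor 1, rose from 10.9 ± 4.40 to 569 ± 231 CPM (5.72 ± 0.52, adjusted p = 0.0480), and Fam20c, a secretory kinase, from 48.2 ± 24.2 to 522 ± 155 CPM (3.46 ± 0.44). Ratios from few WT counts were 91.0 for Colec12 (370 against 1, interval 16.2 to 3604), 62.7 for Flt1 (510 against 2, 17.3 to 519), 45.7 for Ctse (186 against 1, 8.11 to 1816), 38.7 for Cd300lf (315 against 2, 10.6 to 321) and 29.1 for Tnfsf8 (237 against 2, 7.98 to 242). Cst7 (243 against 1, 59.8, 10.6 to 2370.2) and H2-K1 (111 against 1, 27.3, 4.80 to 1088) missed the threshold (0.0659 and 0.0623). The largest falls were the transcription factor Zfp521 (-3.24 ± 0.40), Plch2 (-3.03), the calcium channel subunit Cacna2d2 (-3.02), Pcsk5 (-2.96), Gfra1 (-2.92), Pknox2 (-2.87), Faxc (-2.87, 0.0548 without mouse 417) and Nedd4 (-2.74). Reln, the reelin of Cajal-Retzius cells, fell by 2.18 on the log2 scale. Cajal-Retzius markers in this class summed to 1958 and 2418 CPM in mice 417 and 514 (WT) against 429 and 478 CPM in 418 and 480 (5XFAD). Postsynaptic density genes summed to 13272 CPM in mouse 417 against 2600, 2379 and 1907 CPM in 514, 418 and 480. The falls therefore cannot be told apart from more neuronal RNA in the WT nuclei of this class. No gene passed by edgeR without mouse 418 or 480 or at the other Leiden resolutions (DESeq2 345 with all mice, 1301 at an unadjusted p under 0.05), and 351 and 1889 passed without mice 417 and 514.

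Lists within classes passed camera only at its preset correlation, 2 of 21 in dentate granule-like to 11 of 23 in inhibitory neuron-like nuclei, and none with an estimated correlation. Reactive astrocyte genes were higher in astrocyte-like nuclei (4 measured, median 1.58, adjusted p = 1.52e-10, adjusted p = 0.618 with an estimated correlation). The same list was higher in oligodendrocyte-like (4 measured, median 2.94, adjusted p = 4.21e-13, adjusted p = 0.398 with an estimated correlation) and inhibitory neuron-like nuclei (5 measured, median 1.37, adjusted p = 1.45e-10, adjusted p = 0.297 with an estimated correlation). Adjusted over the list alone, 3, 4 and 3 members rose. Disease-associated oligodendrocyte genes were higher in oligodendrocyte-like nuclei (median 3.37, adjusted p = 6.33e-09, 0.043 by fry, adjusted p = 0.398 with an estimated correlation). In inhibitory neuron-like nuclei their median was 1.37 (adjusted p = 8.33e-17, adjusted p = 0.292 with an estimated correlation). All 19 disease-associated microglia genes measured were higher in microglia-like nuclei (median 1.83, adjusted p = 8.79e-13), 7 of them risen adjusted over the list alone. Disease-associated oligodendrocyte genes were higher there too (median 2.23, adjusted p = 0.00103, too few members measured to test without mouse 418 or 480), while Cajal-Retzius (median -2.18, adjusted p = 9.19e-07) and presynaptic genes (median -1.28, adjusted p = 3.51e-05) were lower. Mouse 417 stood apart in presynaptic genes, at 4580 CPM against 1909 (514), 1145 (418) and 911 CPM (480), and the list passed without it. These 4 had adjusted p = 0.553 with an estimated correlation, and microglia markers had a median of -0.14. Postsynaptic density genes were lower in oligodendrocyte-like (median -1.71, adjusted p = 8.47e-10, adjusted p = 0.503 with an estimated correlation) and astrocyte-like nuclei (median -1.06, adjusted p = 1.15e-06, adjusted p = 0.618 with an estimated correlation). Mouse 417 stood apart in both, with sums of 12274 CPM against 4033, 3665 and 3342 CPM and of 11316 against 4484, 4623 and 4760.0 CPM in mice 514, 418 and 480. Without it the call was lost in astrocyte-like (0.801) and not in oligodendrocyte-like nuclei. Astrocyte markers were lower in dentate (median -0.77, adjusted p = 2.77e-05, adjusted p = 0.908 with an estimated correlation) and inhibitory neuron-like nuclei (median -1.37, adjusted p = 9.61e-13, adjusted p = 0.297 with an estimated correlation). In dentate nuclei their sum was 743 CPM in mouse 417, which stood apart, against 440, 339 and 334 CPM in mice 514, 418 and 480. In CA1-like nuclei, CA3 markers were higher (median 0.43, adjusted p = 2.64e-05) and inhibitory markers lower (median -1.05, adjusted p = 8.8e-05), each with adjusted p = 0.751 with an estimated correlation; without mouse 514 the first was at 0.0502. Sums of the inhibitory markers overlapped between the genotypes (837 and 551.2 CPM in WT, 306 and 551.5 CPM in 5XFAD).

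To describe synaptosomes from a density gradient, compartments of the 1 male (mouse 778) were set beside those of the 2 WT females, without a test since sex, age and preparation differ together. CPM here are per counts without rRNA-like genes, unlike those above. Myelin transcripts were higher. Mbp, myelin basic protein, stood at 20590.3 CPM against 1009.7 and 3007 CPM in mice 417 and 514 (20.4- and 6.85-fold) and Mobp at 4785 against 267 and 728 CPM (17.9- and 6.57-fold). Plekhb1 (10.4 and 6.12), Bcas1 (17.8 and 5.35), Lpar1 (9.67 and 7.09), Pde8a (7.78 and 7.86), Gjc3 (6.71 and 5.21) and Qdpr (11 and 5.03) were others of the 12 genes at least 4 times higher than in both. Xist had 0 counts, at least 83.5- and 156-fold lower. Summed oligodendrocyte markers were 13.3 and 5.51 times the levels in mice 417 and 514, and 2.74 and 1.71 times without Mbp and Mobp. Choroid markers were 7.86 and 2.48 times as high (2.53 and 1.04 without Ttr), endothelial markers 2.97 and 2.29 times and astrocyte markers 1.43 and 1.49 times. Presynaptic (0.983 and 0.925), postsynaptic density (1.19 and 0.938) and dendritic genes (1.35 and 1.01) were close to WT levels, and oxidative phosphorylation (0.753 and 0.575) and nuclear-retained lncRNA genes (0.583 and 0.712) lower. Camk2a (8112 against 5804 and 9488 CPM) lay between the 2 mice, and App (1048 against 1154 and 1232), Thy1 (497 against 519 and 633) and Malat1 (192 against 419.5 and 342) lay below both.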

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

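The tests of the astrocyte markers within the astrocyte class and in compartments were chosen only after the result was seen; the outlier bound and the interaction test were planned.

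Library 2 of mouse 514 had a median of 39104 counts per barcode, far above the other libraries of WT nuclei. Of 19 groups of libraries or of mice tested in this way, chance alone would put about 5% past the same bound. It is also 1 of the 2 libraries in which the doublet caller marked a large share of nuclei (67.5%).

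The genotype effect differed between compartments and nuclei for 13 lists by camera, and for none with an estimated correlation. The pattern with the lowest p was that of astrocyte markers, which fell in nuclei (median -1.35) and stood at -0.38 in compartments. A candidate explanation is that fewer nuclei with astrocyte RNA passed the 5XFAD sort. Within astrocyte-like nuclei the markers had a median of 0.10, but the class is named by these markers, so that value decides nothing. A lower level of astrocyte RNA in the tissue cannot be told apart either: the value of -0.38 in compartments lies above the nuclear median by more than 2 standard errors (0.36 each) but by less than the SD of the markers (1.14), which went both ways, and the bound used, the SD, was set after that value was known. Summed markers were 2973 and 2990 CPM (WT) against 1456 and 946 CPM (5XFAD) in nuclei. In compartments they were 10162 and 9983 against 9823 and 9071 CPM. Medians were also negative in microglia- (-2.32), inhibitory neuron- (-1.37), oligodendrocyte- (-1.15), dentate- (-0.77), CA1- (-0.42) and OPC-like nuclei (-0.22). Mixed astrocyte clusters took 11.7% and 21.7% of WT and 3.07% and 3.62% of 5XFAD nuclei. The sort, the tissue, RNA shared between particles and the depth per nucleus stay open, and a biological loss was not tested.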

How the results depend on the processing

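The alternatives that draw nuclei at random, leave out microglia clusters, thin, use the block on exon counts, set aside the doublet calls of 2 libraries or leave out 1 mouse in tests of lists were chosen after the data had been seen. Over 151 values of named genes, 2141 of 2462 alternative values kept direction and side of the threshold, 219 lost the call, 86 gained one and 16 reversed; 25 more changed sign with neither value past the threshold. Where no reason is given, the cause was not tested.

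Compartments against nuclei gave 2131 genes on intron counts and 11362 to 12334 with 1 mouse left out. On intron counts the log2 folds of Fth1 (-0.95), Nrgn (-0.45), Camk2a (-0.039), Kif5a (-0.15), Rab3a (-0.87), Cplx2 (-0.065), Cox6a1 (-4.77), Ctsb (-0.59), App (-0.040) and Meg3 (1.95) reversed. With the mouse as replicate block the intron share difference was -71.8 (p = 0.125, the smallest possible); without 1 mouse it ran from -72.6 to -70.8. With the block 12797 genes differed, 12612 of them shared with the 13121 without it, and the calls of the 3 lists given above changed. No paired analysis was possible within genotype comparisons because each mouse has 1 genotype.

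In nuclei the count was 1455 with library size alone, 1877 with no low-count filter, 8 with equal class numbers, 40 without microglia clusters, 401 and 334 in 2 random draws, and 607 to 695 with 1 mouse left out. Hsp90ab1 (0.41) and Hsp90aa1 (1.33) reversed on intron counts, and Cx3cr1 (-0.29), Csf1r (-0.50), Ctss (-0.21) and Inpp5d (-0.26) with equal class numbers. In compartments it was 308 with no filter, 67 by DESeq2, 52 on exon counts, 1 on intron counts, 73 with all 8 sums in 1 fit and 8 (without 417) to 310 (without 514) with 1 mouse left out. The interaction gave 301 with no filter, 59 by DESeq2, 3 with the block on exon counts and 0 to 20 (without 514) with 1 mouse left out.

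In classes DESeq2 called 3 (CA1), 7 (OPC), 7 (dentate), 0 (inhibitory), 345 (microglia) and 18 genes (oligodendrocyte). With no low-count filter the counts were CA1 151, OPC 100, astrocyte 208, dentate 163, inhibitory 136, microglia 1213 and oligodendrocyte 753. Leiden 0.5 gave 0 in microglia; Leiden 2 gave 1 in CA1, 105 in OPC and 0 in microglia. With doublets kept it was 1 in CA1 and 240 in astrocytes, and with the calls of 2 libraries set aside 1 in CA1, 2 in inhibitory neurons and 0 in microglia. Ranges with 1 mouse left out were CA1 12 to 70, OPC 64 to 168, astrocyte 0 to 478, dentate 0 to 374, inhibitory 1 to 289, microglia 0 to 1889 and oligodendrocyte 0 to 1553, the ends as named for each mouse above.

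An estimated correlation left 0 lists in every comparison and class; fry gave 23 for compartments against nuclei, 1 in nuclei, 1 in oligodendrocytes and 0 elsewhere. With 1 mouse left out, lists that passed numbered 12 to 15 for compartments against nuclei, 8 to 18 in nuclei, 14 to 18 in compartments, 11 to 15 in the interaction, 3 to 7 in CA1, 2 to 7 in OPC, 3 to 9 in astrocytes, 1 to 11 in dentate, 10 to 13 in inhibitory, 7 to 12 in microglia and 6 to 10 in oligodendrocytes. The microglia share differed by 8.39 percentage points with doublets kept, when WT mice held 0 and 1 such nuclei, and by 9.41 with the calls of 2 libraries set aside. At 2 times in place of 4, 74 genes set the gradient sample apart. No count of genes came from microglia with doublets kept or OPC at Leiden 0.5 and no mitochondrial share could be had, and a minimum of 500 counts removed no nucleus. Compartments held fewer counts than nuclei, and a 2-fold change was recovered less often there on simulated data (19% against 56%).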

Other observations

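The tests of presynaptic genes, of equal class numbers and random draws, and of other splits of the samples were chosen only after the result was seen. The comparison of exon with intron folds in nuclei and the expectation for thinning were written beforehand, although thinning itself was added after the data had been seen.

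Further lists differed within nuclear classes by camera, and none of them with an estimated correlation. In inhibitory neuron-like nuclei, oligodendrocyte (median log2 fold 0.38, adjusted p = 0.000124) and OPC markers (median 0.47, adjusted p = 0.00535) were higher in 5XFAD, each with adjusted p = 0.567 with an estimated correlation. The first did not pass without mouse 417 (0.275), nor the second without 480 (0.955, with the direction turned). Immediate-early genes were lower there (-0.58, adjusted p = 0.374 with an estimated correlation). In oligodendrocyte-like nuclei all 10 oligodendrocyte markers were higher (median 0.27, adjusted p = 0.0474, adjusted p = 0.633 with an estimated correlation) and presynaptic (median -1.21, adjusted p = 1.91e-07) and excitatory genes (median -1.24, adjusted p = 0.00257) were lower, each with adjusted p = 0.503 with an estimated correlation. Mouse 417 stood apart in presynaptic genes (3588 CPM against 1220, 1180 and 958 CPM in mice 514, 418 and 480), and the list passed without it. Without mouse 417 the oligodendrocyte markers (0.716) and excitatory genes (0.0885) lost their calls, and so did the former without 418 (0.167). In astrocyte-like nuclei, presynaptic genes (median -0.81, adjusted p = 1.15e-06) and nuclear-retained lncRNA (median -1.23, adjusted p = 0.00912) were lower, with adjusted p = 0.618 with an estimated correlation. Mouse 417 stood apart in presynaptic genes (3337 CPM against 1524, 1308 and 1447 CPM in mice 514, 418 and 480), and without it neither list passed (0.213 and 0.801), nor the second without 418 (0.19). CA1-like nuclei held less of postsynaptic density (median -0.19, adjusted p = 0.00108), dentate (median -0.43, adjusted p = 0.0132) and CA1 marker genes (median -0.21, adjusted p = 0.00923), with adjusted p = 0.751 with an estimated correlation. Sums overlapped between the genotypes for dentate (1063 and 773 CPM in WT, 392 and 1016 CPM in 5XFAD) and CA1 markers (2798 and 2960 CPM, 3005 and 2026 CPM). The 3 calls were lost without mouse 417 (0.527 for the first and 0.16 for the second list), 514 (0.152 for the third), 418 (0.574 for the second, with the direction turned) or 480 (0.243 for the first and 0.745 for the third).

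App stood higher in 5XFAD compartments on exon counts and not on intron counts. A candidate explanation is that spliced transgene mRNA, which carries no introns of the gene, was counted on the mouse gene. In nuclei the exon fold lay above the intron fold by 2.03 standard errors, which that explanation needs and which is barely past the bound of 2. That error takes the exon and intron folds as independent, although both come from the same mice. A value so close to the bound therefore cannot decide. More neuronal RNA in the compartments is argued against, since the median fold of presynaptic genes was 0.075, far below the 1.53 of App. Thy1 rose on introns as well, which may reflect mouse Thy1 sequence in the transgenes, and this was not tested.

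The 799 genes that differed between 5XFAD and WT nuclei fell to 8 with equal numbers of each named class, below all 5 random draws of as many nuclei (lowest 334). The draws, also taken from named classes, held 327 to 582 rises and 7 to 82 falls, against 560 and 239 with all nuclei. Different shares of cell classes between the genotypes are therefore a candidate explanation for the rises seen in the draws. For the falls the comparison cannot decide, since most were already missing from the draws. Nor can it speak for genes that differ through mixed or unnamed nuclei. Different total counts of the mice are argued against, since thinning every mouse to the lowest total left 815 genes. C4b and Thy1 passed with equal class numbers too, so shares of the named classes do not account for these genes. Whether the shares reflect the tissue or the sort was not tested.

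Among the 8 splits of the 8 sums that part all 4 mice, 1 gave as many genes as the real split of compartments and nuclei, which was the real one itself. It gave 12827 genes in a fit of 2 groups, and the highest other gave 0; the splits are too few for a share under 0.05.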
